A study of Mus musculus with 12 samples.

How the data were processed

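Total RNA of 12 cultures was labelled as biotinylated cRNA and hybridised to Affymetrix Mouse430A_2 arrays, per the labels' protocols, with 4 arrays for each of the groups Fibro (fibroblasts), iAstro (fibroblasts infected with NFIA, NFIB and SOX9) and Astro (primary astrocytes). The deposited values were log2 expression levels made with RMA in the affy package, per the submitters' processing notes, which give no versions. The table held 22690 probe sets, with values from 2.33 to 14.65, and the median over probe sets of the mean value was 7.09. The spread of the values and their like quantiles across arrays were checked and fitted a log2 scale. The raw intensities were not used here, so the background correction and normalisation were taken as deposited. Signal over background was judged from 3 probe sets for bacterial trp controls, which read 2.72 to 3.91.

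Probe sets were given genes by the array annotation supplied with the series: 20393 had 1 gene symbol, 691 had several and 1606 had none. Of the single-gene probe sets, 20364 had an Entrez ID present in the RefSeq table for GRCm38.p6, which was used for names alone, 29 had none there, and 0 symbols differed. The table held 64 control probe sets, of which 13 carry a mouse gene symbol and were kept. For each gene the single-gene probe set with the highest mean over the 12 arrays was tested, which left 12394 genes. Where other probe sets of a named gene gave another call, the text says so.

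A linear model with 3 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (eBayes without trend), and the 3 pairwise contrasts were tested two-sided. A gene was called when its Benjamini-Hochberg adjusted p, over all genes of the comparison, lay under 0.05; a second count took called genes that differed at least 2-fold. Adjusted p-values of genes in the text are of this kind. Log2 fold changes are given with the model's standard error (SE), and group means with the SD of 4 arrays. The p-values reflect the spread among the 4 labelled biological replicates of each group. The labels do not say whether these replicates came from separate animals or separate infections. The series record names 3 replicates per group and the sample labels 4, and all samples were used.

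Before the data were examined, 17 gene lists, the tests, the alternatives and the rule for named genes were fixed. Of 347 list entries 298 were measured. The lists covered astrocyte markers, astrocyte transport and coupling, reactive astrocyte genes, fibroblast markers, myofibroblast and smooth muscle genes, chondrocyte genes, neural progenitor genes, neuron markers, oligodendrocyte lineage markers, microglia and macrophage markers, endothelial markers, ependymal markers, cell cycle genes, interferon response genes, cholesterol synthesis genes, Hox genes, and forebrain and midbrain transcription factors. Some genes stand in more than 1 list. Each list was tested in each comparison with limma's camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, and p-values were adjusted with Benjamini-Hochberg over the 51 combinations. Members were counted as higher, lower or not called over all genes and adjusted over the list alone.

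The rule for named genes allowed, per comparison, the introduced factors, 12 core markers, the 8 largest rises and 8 largest falls among called genes whose 4 arrays of 1 group lay beyond the 4 arrays of the other, up to 3 called members of each list in each direction with up to 2 uncalled members, and the 6 genes highest above and 6 lowest below both control groups. Predicted genes and probe sets of several genes were left out. The text names a selection of the genes that this rule allows, chosen after their values were seen. In the selection tabulated for the text, 66 of 68 called genes of iAstro against Fibro, all 55 of Astro against Fibro and all 60 of iAstro against Astro had 4 of 4 arrays of 1 group beyond all arrays of the other. The rule asked for this of the largest rises and falls and favoured large changes elsewhere, so these counts do not test the calls.

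The conversion score projected each array onto the line from the Fibro mean (0) to the Astro mean (1) over genes called and at least 2-fold apart between these groups, with each Fibro and Astro array scored against means that left it out. Scores of groups were compared with an exact two-sided permutation test. The overlap of both comparisons with Fibro was set against independent lists of the same sizes and against splits of the Fibro arrays between the comparisons, and the covariance of their fold changes against 100 simulations of unchanged groups with shared Fibro arrays. Shares of genes carry an exact binomial (Clopper-Pearson) interval, which treats genes as independent.

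The steps were tested on simulated data with the real genes' means and spreads, in which 200 of 12394 genes were changed. For iAstro against Fibro 92.5% of genes changed 1.5-fold, 100% of those changed 2-fold and 100% of those changed 4-fold were called, with 8 calls among unchanged genes. For Astro against Fibro the shares were 92.5%, 97% and 100%, with 7 calls among unchanged genes, and for iAstro against Astro 94%, 97% and 100%, with 12. A simulated score of 0.3, with every gene placed that share of the way, was found as 0.3. In iAstro against Fibro 1 of 1 shifted lists and 0 of 16 others were called. The simulated noise was independent between genes, and gene calls were tested with few genes changed. These checks therefore do not show how the steps behave with correlated genes or with most genes changed.

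The alternatives were a replicate block, a fit of the 8 arrays compared, eBayes with trend and robust variances, array weights, quantile normalisation applied again, alignment of array medians, leaving out genes whose highest group mean lay under 7.09, the mean of a gene's probe sets, leaving out probe sets marked _x or _s, testing every probe set, a floor of 1.2-fold (limma treat), and leaving out each array in turn. For the score the axis genes, the weight per gene and splits of the control arrays were varied as well. Leaving out iAstro replicates 2 and 4 together was added after their control probe sets were seen. The closing section gives the effect of these alternatives.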

Results

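Gene expression was measured on Affymetrix Mouse430A_2 arrays in 12 samples of mouse cells of the FVB strain, 4 arrays in each of 3 groups. The groups were fibroblasts (Fibro, the negative control), induced astrocytes (iAstro, fibroblasts infected with the transcription factors NFIA, NFIB and SOX9) and primary astrocytes (Astro, the positive control). All samples were grown for 12 days in the same medium, per the labels, which do not say whether the Fibro cells received a control virus. The series record names 3 biological replicates per group, whereas 4 samples per group are labelled as biological replicates, and all 12 were used. Values were log2 expression levels between 2.33 and 14.65, and 12394 genes were tested, each through 1 probe set. The number of arrays limits the precision of every value: the median standard error of a log2 fold change was 0.0684 (n = 4 per group).

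The 3 groups were clearly separated. Arrays of 1 group correlated with a mean r across all probe sets of 0.998 in Fibro, 0.998 in Astro and 0.996 in iAstro. The mean r was 0.953 between iAstro and Fibro, 0.933 between iAstro and Astro and 0.924 between Astro and Fibro. Probe sets are not independent replicates. The first principal component held 63.1% of the variance and set Astro apart from both other groups, and the second held 33.7% and set iAstro apart from Fibro. In the control probe sets for pyruvate carboxylase, the 3′ reading exceeded the 5′ reading by 0.98 ± 0.085 on the log2 scale in Fibro (SD, n = 4), by 2.10 ± 0.64 in iAstro (range 1.44 to 2.78) and by 1.79 ± 0.19 in Astro. The same difference for beta-actin was −0.01 ± 0.031 in Fibro, 0.17 ± 0.086 in iAstro and 0.06 ± 0.0065 in Astro, and the control for Gapdh gave −0.27 ± 0.018 in Fibro, −0.18 ± 0.061 in iAstro and −0.23 ± 0.0086 in Astro. For all 3 controls every iAstro array and every Astro array lay above every Fibro array.

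The introduced factors were read unequally. Nfia had 3 probe sets. The first rose from 4.45 ± 0.18 in Fibro to 10.52 ± 0.98 in iAstro (log2, SD, n = 4), 67.1-fold, and another rose 41.3-fold (adjusted p = 4.67e-09 and 5.18e-09 in the fit of every probe set). The Nfia probe set with the highest mean, which the rule for 1 probe set per gene chose, read 7.55 ± 0.24 in Fibro, 7.82 ± 0.10 in iAstro and 9.79 ± 0.18 in Astro, and its difference between iAstro and Fibro did not pass the test (log2 fold change 0.27 ± 0.11 SE, adjusted p = 0.0536). It passed without Fibro replicate 3 (0.38, adjusted p = 0.00693) and without iAstro replicate 1 (0.32, adjusted p = 0.0422). It also passed with trend and robust variances (adjusted p = 0.0439) and with dim genes left out (adjusted p = 0.0383). The mean of the 3 Nfia probe sets passed as well (3.9, adjusted p = 2.96e-09). Nfib read 10.04 ± 0.13 in Fibro, 10.16 ± 0.17 in iAstro and 10.50 ± 0.098 in Astro, with no call between iAstro and Fibro (log2 fold change 0.12 ± 0.087, adjusted p = 0.253). Of its other 3 probe sets, 1 was called lower in iAstro than in Fibro. Sox9 fell in iAstro, by 0.89 ± 0.068 on the log2 scale (adjusted p = 7.32e-08), and its other probe set fell by 1.34, whereas Sox9 was 2.49-fold higher in Astro than in Fibro. Where these probe sets lie relative to the introduced sequences is not given in the sources used here, so a low reading does not show that a factor was absent.

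The comparison of iAstro with Fibro asked what infection with the 3 factors changed. Most measured genes of the reactive astrocyte state, of the interferon response and of cartilage matrix rose, and genes of the contractile cytoskeleton fell. The largest rise was in Lcn2, a secreted iron-binding protein of reactive astrocytes, 260-fold (log2 fold change 8.02 ± 0.13 SE, n = 4 per group, adjusted p = 8.83e-15). It was followed by the matrix protease gene Mmp3 (194-fold), Spon1 (174-fold), the acute-phase gene Saa3 (146-fold) and Olig1, a transcription factor of the oligodendrocyte lineage (106-fold). The largest fall was in Cnn1, which encodes smooth muscle calponin, by 7.40 ± 0.052 on the log2 scale (adjusted p = 1.4e-17), with Rgs4, Rgs5 and Acta1 next (121-fold, 118-fold and 63.6-fold lower). In limma's test 7458 of the 12394 genes were called (60.2%), 3163 higher and 4295 lower in iAstro, and 1380 of them differed at least 2-fold, 862 higher and 518 lower. The fit limited to a change of 1.2-fold or more called 3668 genes, 1879 higher and 1789 lower. With array medians aligned 2786 were higher and 5231 lower, so the balance of rises and falls depends on the setting. The 3′ minus 5′ difference of all 3 control genes was larger in all 4 iAstro arrays than in all 4 Fibro arrays, and without iAstro replicates 2 and 4, where that of pyruvate carboxylase was largest (2.78 and 2.49), 7019 genes were called.

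Astrocyte markers rose as a group in iAstro, but unevenly. Of 32 measured members 20 rose, 3 fell and 9 were not called, with a median log2 fold change of 0.48 (camera, adjusted p = 3.44e-06). The glycolytic enzyme gene Aldoc rose 78.6-fold, the calcium-binding protein gene S100b 18.5-fold (4.21 ± 0.069), the proteoglycan gene Bcan 17.7-fold, Fabp7 11.3-fold and the glutamine synthetase gene Glul 3.19-fold. S100b was not called between Astro and Fibro (−0.04 ± 0.069, adjusted p = 0.608), so its rise was not a move towards the Astro level. Gfap, the intermediate filament gene of astrocytes, rose 1.93-fold, from 4.74 ± 0.28 to 5.69 ± 0.050 (adjusted p = 5.22e-06), and the glutamate transporter genes Slc1a3 and Slc1a2 rose 1.84-fold and 1.54-fold. The gap junction gene Gja1 rose 1.36-fold, and of its other 5 probe sets 3 were called higher and 2 were not called. The members that fell were the transcriptional regulator gene Id4 (10.9-fold lower), Ntsr2 (1.52-fold lower) and Slc7a10 (1.32-fold lower, adjusted p = 0.0364). The call of Slc7a10 was lost without Fibro replicate 1 (−0.35, adjusted p = 0.0911), without Fibro replicate 4 (−0.33, adjusted p = 0.1) and without iAstro replicate 2 (−0.22, adjusted p = 0.0818). Aldh1l1 and the water channel gene Aqp4 were not called (log2 fold changes 0.11 ± 0.081 and −0.11 ± 0.063). Aldh1l1 passed without iAstro replicate 2 (0.20, adjusted p = 0.0094) and Aqp4 without Fibro replicate 2 (−0.17, adjusted p = 0.0269). Aqp4 read 3.25 ± 0.10 in iAstro and 3.36 ± 0.12 in Fibro, within the range of the bacterial control probe sets (2.72 to 3.91).

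Of 12 measured genes of astrocyte transport and coupling, 8 rose and 4 were not called (median 0.56, adjusted p = 0.0043). This list call was lost (adjusted p = 0.0631 with an estimated correlation, and 0.0964 with dim genes left out). Among 30 reactive astrocyte genes 19 rose, 6 fell and 5 were not called (median 1.23, adjusted p = 1.16e-05). The ceruloplasmin gene Cp rose 69.4-fold and the protease inhibitor gene Serpina3n 68.0-fold, while the heat shock protein gene Hspb1 was 4.67-fold lower, and Vim, near the top of the array's range at 14.12 and 14.19, was not called (−0.07 ± 0.034, adjusted p = 0.0954), although all 4 iAstro arrays lay below all 4 Fibro arrays. Vim passed as lower with trend and robust variances (adjusted p = 0.00442), with array medians aligned (−0.13, adjusted p = 0.0088) and with dim genes left out (adjusted p = 0.0444). All 14 measured interferon response genes rose (median 2.26, adjusted p = 1.27e-11), among them Ifit1 (32.7-fold), Oasl2 (29.6-fold) and Usp18 (26.8-fold).

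Genes of cartilage formed the list with the largest median rise. Of 19 measured chondrocyte genes 17 rose and 2 fell (median 3.39, adjusted p = 5.57e-10). The cartilage collagen genes Col9a3 and Col9a1 rose 52.1-fold and 44.3-fold and the chondroadherin gene Chad 36.3-fold, whereas Col10a1, a collagen gene of hypertrophic chondrocytes, was 20.5-fold lower and Comp 2.10-fold lower. Of 29 fibroblast markers 11 rose, 12 fell and 6 were not called, and camera, which compares a list with other genes, did not call the list (median 0.01, adjusted p = 0.719). Their mean was 11.34 ± 0.020 in Fibro and 11.74 ± 0.039 in iAstro (log2, SD, n = 4), and fry, which makes no such comparison, called the list higher (adjusted p = 3.44e-08). The small leucine-rich proteoglycan genes Dcn and Lum rose 39.9-fold and 22.7-fold and Dpt 19.4-fold, whereas the matrix genes Mfap5 and Fbln2 were 3.18-fold and 2.77-fold lower and Thy1 1.62-fold lower. Col3a1 rose 1.29-fold, and Col1a1 was not called (0.13 ± 0.069), with a call for its other probe set (−0.35) and for the same probe set without iAstro replicate 2 (0.19, adjusted p = 0.0175). All 12 myofibroblast and smooth muscle genes fell (median −2.99, adjusted p = 1.84e-09), including Myh11 (26.2-fold lower), Myl9 (20.2-fold lower) and Tagln (19.4-fold lower).

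Cell cycle genes fell in iAstro: 21 of 24 were lower, 2 higher and 1 not called (median −0.96, adjusted p = 1.92e-07, and adjusted p = 0.0134 with an estimated correlation). Ccnb2, which encodes a mitotic cyclin, was 3.86-fold lower and the mitotic checkpoint kinase gene Bub1 2.91-fold lower. The 2 higher members, Mcm7 (0.23 ± 0.051) and Tyms (0.19 ± 0.076, adjusted p = 0.0471), depended on the settings: of the other 3 Mcm7 probe sets 1 was called higher, 1 lower and 1 not called, Mcm7 read −0.04 without probe sets marked _x or _s, and Tyms kept no call when any of 9 single arrays, all but Fibro replicate 1, iAstro replicate 1 and Astro replicate 4, was left out (adjusted p = 0.0515 to 0.133). Tyms read 3.50 ± 0.16 in iAstro and 3.32 ± 0.086 in Fibro, within the range of the bacterial control probe sets, so its count as higher here and against Astro rests on background readings. Against Astro the other 2 Tyms probe sets were not called. All 14 cholesterol synthesis genes fell (median −1.05, adjusted p = 1.19e-07), with Idi1 3.00-fold lower and Fdps 2.62-fold lower, though the other Fdps probe set was not called. Of 24 Hox genes, which mark position along the body axis, 15 rose, 1 fell and 8 were not called (median 0.37, adjusted p = 8.75e-04). Hoxc8 rose 3.92-fold and Hoxa11 was 1.22-fold lower, while Hoxa9 (0.16 ± 0.088) and Hoxa10 (0.19 ± 0.19) were not called, although all 4 iAstro arrays lay above all 4 Fibro arrays. Both passed in the fit of the 8 arrays compared (adjusted p = 0.011 and 0.0125), which leaves out the Astro arrays, where the SD of Hoxa10 was 0.54. Hoxa9 passed without Astro replicate 1 (0.16, adjusted p = 0.0464), and the Hox list call was lost with dim genes left out (adjusted p = 0.193).

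Camera did not call the lists for other cell types between iAstro and Fibro, whereas fry called each of these 7 lists (adjusted p = 1.23e-09 to 0.0407). Of 15 neural progenitor genes 5 rose and 4 fell (adjusted p = 0.649), of 18 neuron markers 2 rose and 8 fell (adjusted p = 0.252), and of 18 microglia and macrophage markers none rose and 4 fell (adjusted p = 0.391). Among 11 oligodendrocyte lineage markers 3 rose and 3 fell (adjusted p = 0.572), the former including Olig1, Olig2 (2.11-fold) and Cnp (7.11-fold). Mbp was not called by the chosen 1 of its 8 probe sets (−0.10), whereas 5 others were called higher and 2 were not called. With the mean of probe sets the list stayed uncalled. Endothelial markers had 3 higher and 3 lower of 13 (adjusted p = 0.711), with Kdr and Flt1 3.64-fold and 3.14-fold higher, and ependymal markers had 2 lower of 4 (adjusted p = 0.244). Of 9 forebrain and midbrain transcription factors 3 rose and 1 fell (adjusted p = 0.562). The neuronal gene Stmn2 was 4.32-fold lower. Of these lists, the neural progenitor, oligodendrocyte, endothelial and forebrain lists had a negative median (−0.03, −0.10, −0.12 and −0.02) beside a test direction and a mean above 0.

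**Figure D1:**
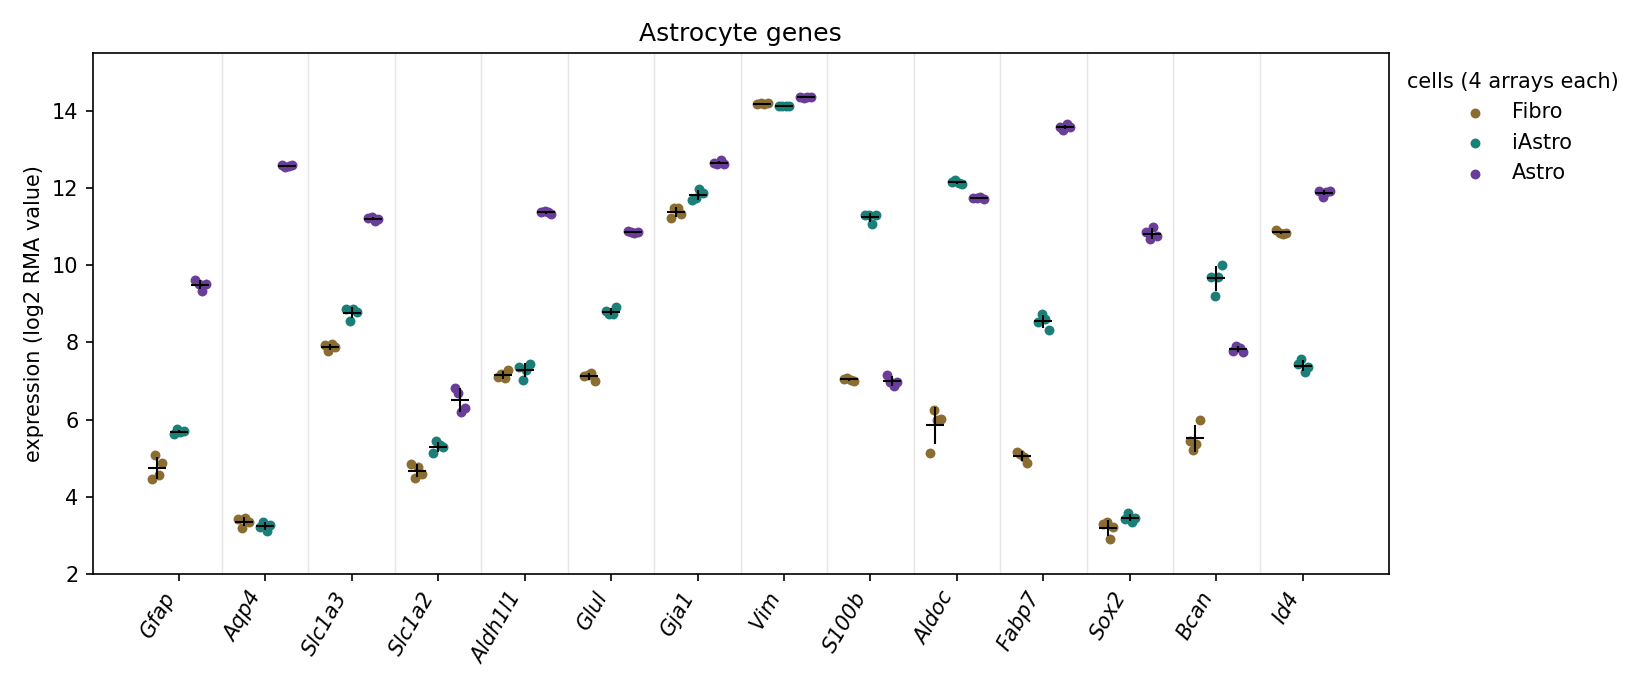
Log2 expression of 14 astrocyte genes (vertical axis, log2 RMA value) in the 4 arrays of each group, each point 1 array, with the mean (horizontal bar) and SD (vertical bar). S100b and Bcan lie highest in iAstro, whereas Gfap, at a mean of 5.69 in iAstro, and Aqp4, at 3.25, lie far below the Astro means of 9.50 and 12.57.

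The comparison of Astro with Fibro asked how far the control groups lie apart. Aqp4 was 594-fold higher in Astro (log2 fold change 9.22 ± 0.063 SE, n = 4 per group, adjusted p = 1.05e-17), followed by Fabp7 (369-fold), Olig1 (355-fold), Lcn2 (354-fold) and Mlc1, which encodes a membrane protein of astrocyte endfeet (267-fold). The Wnt modulator gene Sfrp2 was 918-fold lower (−9.84 ± 0.13), with Aspn 656-fold and Comp 335-fold lower. Gfap was 27.1-fold higher (4.76 ± 0.11), Aldh1l1 18.5-fold, Glul 13.4-fold and Slc1a3 9.97-fold. S100b did not differ by call, reading 7.0 ± 0.13 in Astro and 7.04 ± 0.038 in Fibro (−0.04 ± 0.069, adjusted p = 0.608), and its other probe set was called lower in Astro (−0.47). In all, 8523 genes were called, 3847 higher and 4676 lower in Astro, and 2008 of them differed at least 2-fold, 1187 higher and 821 lower. With the floor of 1.2-fold 4709 genes were called, 2436 higher and 2273 lower, and with array medians aligned 3552 were higher and 5178 lower. The 3′ minus 5′ difference of all 3 control genes was larger in all 4 Astro arrays than in all 4 Fibro arrays.

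Of 32 astrocyte markers 28 were higher in Astro and 1 lower (median 3.61, adjusted p = 2.1e-14), the latter Cst3 (−0.14 ± 0.037), whose call was lost when the arrays were quantile normalised again (−0.04, adjusted p = 0.391). For transport and coupling 11 of 12 were higher, including the potassium channel gene Kcnj10 (36.2-fold; list adjusted p = 1.47e-07), and for reactive astrocyte genes 23 of 30 were higher and 5 lower, with Cp 179-fold higher (adjusted p = 5.75e-07). Neural progenitor genes were higher in 12 and lower in 2 of 15 (adjusted p = 7.61e-06), with Sox2 198-fold and Prom1 92.2-fold higher. Of 9 forebrain and midbrain transcription factors 6 were higher and 1 lower (adjusted p = 0.00161), with Zic1 113-fold and Otx2 38.6-fold higher, and of 24 Hox genes 14 were lower and none higher (adjusted p = 4.38e-04), with Hoxa9 58.4-fold lower. Of 29 fibroblast markers 28 were lower (median −1.85, adjusted p = 9.26e-13), including Mfap5 (47.9-fold) and Postn (44.9-fold), and 1 was higher, Dcn (3.29-fold). All 12 myofibroblast and smooth muscle genes were lower (adjusted p = 1.62e-06).

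Markers of other cell types also differed between the control groups. Microglia and macrophage markers were higher in Astro for 16 of 18 and lower for 1, Tmem119 (median 2.40, adjusted p = 5.85e-07), with the cathepsin gene Ctss 18.0-fold and the adaptor gene Tyrobp 16.6-fold higher. Neuron markers were higher for 10 of 18 and lower for 3 (adjusted p = 0.00738, and adjusted p = 0.0692 with an estimated correlation), with Gap43 39.0-fold and Stmn2 21.0-fold higher. Ependymal markers were higher for 3 and lower for 1 of 4, with no list call by camera (adjusted p = 0.229), and the ciliogenesis factor gene Foxj1 was 40.8-fold higher. Oligodendrocyte lineage markers (4 higher, 3 lower of 11, adjusted p = 0.385) and endothelial markers (4 higher, 5 lower of 13, adjusted p = 0.946) were not called by camera. Their medians, −0.08 and −0.13, lay opposite to a test direction and a mean above 0. The oligodendrocyte gene Mbp counted as higher by its chosen probe set (0.49), with 3 others called higher and 4 not called.

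Interferon response genes were higher in Astro for 13 of 14 (adjusted p = 2.36e-08), with the chemokine gene Cxcl10 61.0-fold and Oasl2 37.1-fold higher. Cell cycle genes were higher for 20 of 24 and lower for 1, E2f1 (−0.36 ± 0.062), with a median of 0.47 (adjusted p = 1.04e-04). Among them Top2a was 1.88-fold higher, though its other probe set was not called. Cholesterol synthesis genes were lower for 10 of 14 and higher for none (adjusted p = 0.00161, and adjusted p = 0.096 with an estimated correlation), with Fdps 2.48-fold lower by 1 of its 2 probe sets. Chondrocyte genes were lower for 12 of 19 and higher for 3 (adjusted p = 0.00904, and adjusted p = 0.071 with an estimated correlation). Col2a1, the main collagen gene of cartilage, was 48.3-fold lower in Astro, and the 3 higher members were Sox6, Matn4 and Col9a3 (2.75-fold, 1.90-fold and 1.40-fold), though the other 2 Col9a3 probe sets were not called.

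The comparison of iAstro with Astro asked what still separated induced from primary astrocytes. Aqp4 was 643-fold lower in iAstro (−9.33 ± 0.063 SE, n = 4 per group, adjusted p = 8.98e-18), and the proteoglycan gene Ncan (250-fold), Mlc1 (231-fold), the neural stem cell factor gene Sox2 (165-fold) and Bex1 (161-fold) were lower as well. Col2a1 was 341-fold higher in iAstro (8.41 ± 0.12, adjusted p = 1.32e-15), with Sfrp2 256-fold, Col9a1 179-fold and Dpt 170-fold higher. Gfap was 14-fold lower (−3.81 ± 0.11), Aldh1l1 17.1-fold, Slc1a3 5.40-fold, Glul 4.19-fold and Gja1 1.78-fold lower. In all, 7914 genes were called, 3825 higher and 4089 lower in iAstro, and 1973 of them differed at least 2-fold, 970 higher and 1003 lower. With the floor of 1.2-fold 4722 genes were called.

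Of 32 astrocyte markers 25 were lower in iAstro than in Astro, 3 higher and 4 not called (median −2.71, adjusted p = 7.33e-09). The higher members were S100b (19.0-fold), Bcan (3.57-fold) and Cst3 (1.62-fold). Aldoc was not called (0.40 ± 0.17, adjusted p = 0.0543), although all 4 iAstro arrays lay above all 4 Astro arrays. It passed without Fibro replicate 1 (adjusted p = 4.71e-05) and without Fibro replicate 2 (adjusted p = 0.0325), and its other probe set was called higher (1.66). Aldoc also passed in the fit of the 8 arrays compared (adjusted p = 2.04e-05), with a replicate block (adjusted p = 0.0498) and with dim genes left out (adjusted p = 0.0395). The mean of its probe sets passed too (1.03, adjusted p = 2.57e-07). Of 12 transport and coupling genes 10 were lower and 1 higher, Slc7a11 (1.23-fold; list adjusted p = 1.35e-05), with Kcnj10 38.3-fold lower. Neural progenitor genes were lower for 13 of 15 (adjusted p = 9.43e-07), with Pax6 38.2-fold lower (of its other 4 probe sets 3 were called lower and 1 was not called), and forebrain and midbrain factors were lower for 8 of 9 (adjusted p = 2.11e-04), with Zic1 87.5-fold and Otx2 41.9-fold lower. Of 24 Hox genes 22 were higher and none lower (median 0.91, adjusted p = 1.32e-07), with Hoxa9 65.2-fold and Hoxa10 48.4-fold higher.

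All 29 fibroblast markers were higher in iAstro than in Astro (median 2.23, adjusted p = 1.2e-16), among them Dpt, Lum (28.8-fold), Col3a1 (9.26-fold) and Col1a1 (3.45-fold). Chondrocyte genes were higher for 18 of 19 and lower for none (median 5.10, adjusted p = 4.47e-12), with Comp 160-fold and Hapln1 135-fold higher. Myofibroblast and smooth muscle genes were lower for 8 of 12 and higher for 1 (adjusted p = 9.77e-04), with Cnn1 101-fold and Tagln 10.7-fold lower. The higher member, Des (0.23 ± 0.094, adjusted p = 0.0455), lost its call when any of 9 single arrays, all but Fibro replicates 2 and 4 and iAstro replicate 4, was left out (adjusted p = 0.054 to 0.102), and its other probe set was not called (0.02). Cell cycle genes were lower for 22 of 24 and higher for 2 (median −1.52, adjusted p = 4.91e-09), with Ccnb2 4.67-fold lower and Top2a 4.49-fold lower by 1 of its 2 probe sets. Cholesterol synthesis genes were lower for 10 of 14 (adjusted p = 5.65e-04, and adjusted p = 0.071 with an estimated correlation), with Sqle 2.10-fold lower.

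Reactive astrocyte genes split between higher (12) and lower (17) in iAstro among 30, with no list call by camera (adjusted p = 0.3), and interferon response genes had 8 higher and 3 lower of 14 (adjusted p = 0.221), with Usp18 2.11-fold higher and Cxcl10 14.8-fold lower. Microglia and macrophage markers were lower in iAstro for 17 of 18 (adjusted p = 4.25e-07), Ctss by 17.3-fold and Tyrobp by 17.2-fold, and 1 was higher, Tmem119 (9.54-fold). Neuron markers were lower for 12 of 18 and higher for 3 (adjusted p = 0.00479, and adjusted p = 0.0605 with an estimated correlation), with Stmn2 90.5-fold and Gap43 44.8-fold lower. Oligodendrocyte lineage markers (1 higher, 4 lower of 11, adjusted p = 0.413), endothelial markers (3 higher, 3 lower of 13, adjusted p = 0.891) and ependymal markers (1 higher, 3 lower of 4, adjusted p = 0.116) were not called by camera, although Foxj1 was 44.1-fold lower. Among the oligodendrocyte markers Mbp counted as lower by its chosen probe set (−0.59), whereas 6 others were called higher and 1 was not called. For endothelial markers the mean was −0.04 and the median 0.02.

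Adjusted over the list alone, the numbers of members called higher and lower equalled those over all genes in 45 of the 51 combinations of list and comparison. In the other 6 they were 24 higher and 5 lower for reactive astrocyte genes and 0 higher and 12 lower for cholesterol synthesis genes in Astro against Fibro, and 0 higher and 3 lower for microglia and macrophage markers in iAstro against Fibro. In iAstro against Astro they were 4 higher and 25 lower for astrocyte markers, 0 higher and 11 lower for cholesterol synthesis genes and 23 higher and 0 lower for Hox genes. Of the 51 combinations, camera called 35 with the preset correlation and 29 with an estimated correlation, and fry, which compares a list with no other genes, called 50. List p-values in the text are camera's with the preset correlation unless another test is named. The estimated correlation gave much weaker ones, with a smallest adjusted p of 0.00307 against 1.2e-16. For iAstro against Fibro it gave 0.00421 for chondrocyte genes, 0.00421 for interferon response genes and 0.0234 for Hox genes.

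**Figure D2:**
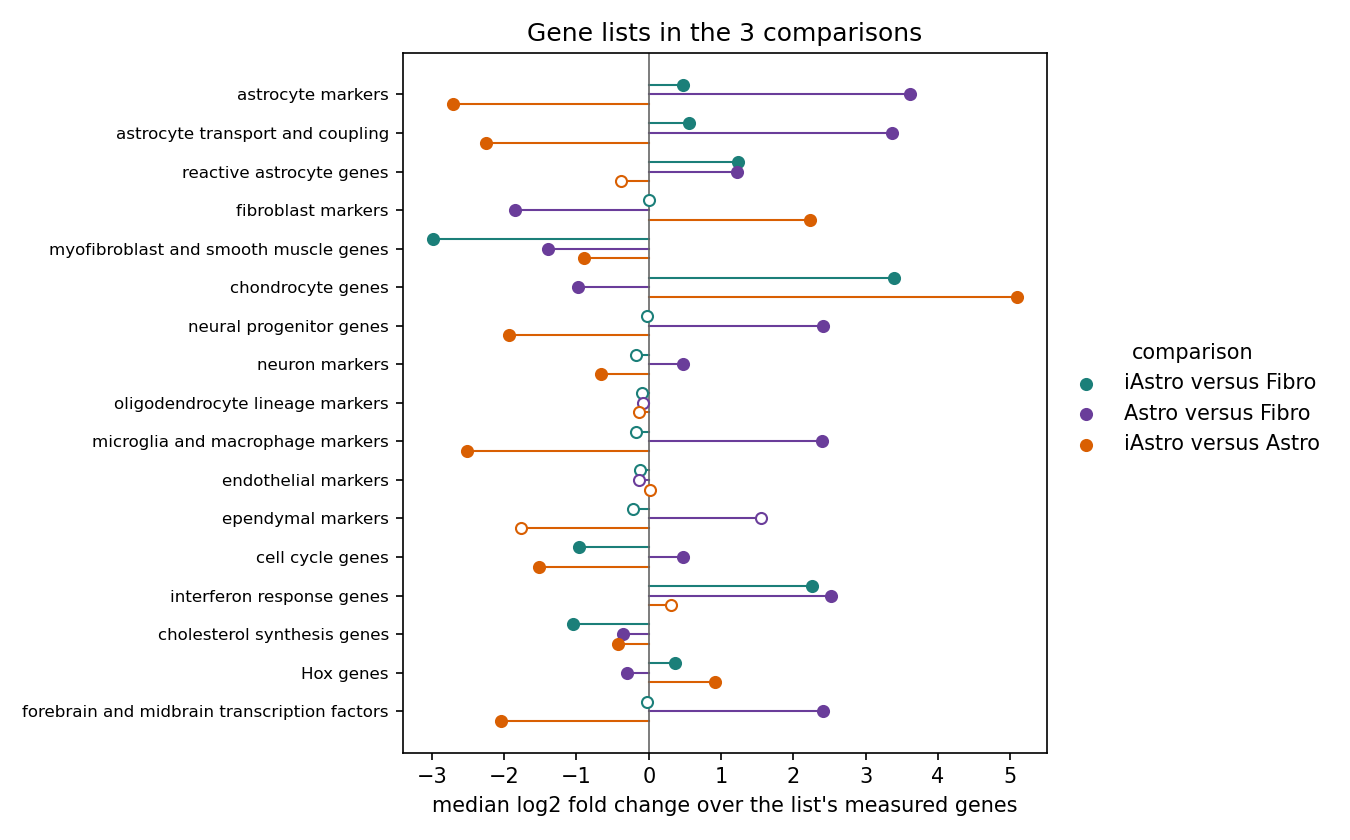
Median log2 fold change (horizontal axis, log2) of the measured genes of 17 lists in the 3 comparisons, with filled points for lists called by camera and open points for lists not called. Chondrocyte genes have medians of 3.39 against Fibro and 5.10 against Astro in iAstro, and astrocyte markers 0.48 and −2.71.

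The conversion score gave each array 1 position between the control groups, with 0 at the Fibro mean and 1 at the Astro mean, over the 2008 genes called and at least 2-fold apart between the control groups. The iAstro arrays scored 0.343 ± 0.0065 (SD, n = 4), against 0.001 ± 0.003 in Fibro and 0.999 ± 0.006 in Astro. The difference from each control group gave p = 0.0286 in an exact two-sided permutation test, the smallest p that 4 arrays against 4 allow. Genes higher in Astro scored 0.369 ± 0.0099 and genes lower in Astro 0.30 ± 0.0061. Over the gene lists the position varied widely. It was 0.906 ± 0.0065 over interferon response genes, 0.738 ± 0.013 over reactive astrocyte genes, 0.207 ± 0.0055 over astrocyte markers, 0.162 ± 0.013 over neural progenitor genes, 0.115 ± 0.013 over forebrain and midbrain factors, 0.095 ± 0.013 over fibroblast markers and 0.084 ± 0.010 over transport and coupling genes. The scores over interferon response and reactive astrocyte genes need not mean conversion. No control virus is stated for Fibro, so an effect of infection cannot be told apart from one of the factors. The Astro cultures also read higher for 16 of 18 microglia and macrophage markers. Myofibroblast and smooth muscle genes lay beyond Astro at 1.266 ± 0.032, and chondrocyte and Hox genes lay on the far side of Fibro, both at −0.061. The chondrocyte score covered only 10 of 19 measured genes. Comp and Col10a1, 335-fold and 232-fold lower in Astro than in Fibro, weighed most and fell in iAstro, which offset rises of other members. The score thus does not show the size of the list's rise (median 3.39 over 19 genes). Microglia and macrophage markers scored 0.013 ± 0.047, not distinguishable from Fibro (exact permutation p = 0.686). The 13 lists with at least 5 genes on the axis also included endothelial markers at 0.406 ± 0.023 and neuron markers at −0.245 ± 0.019, each over 5 genes.

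**Figure D3:**
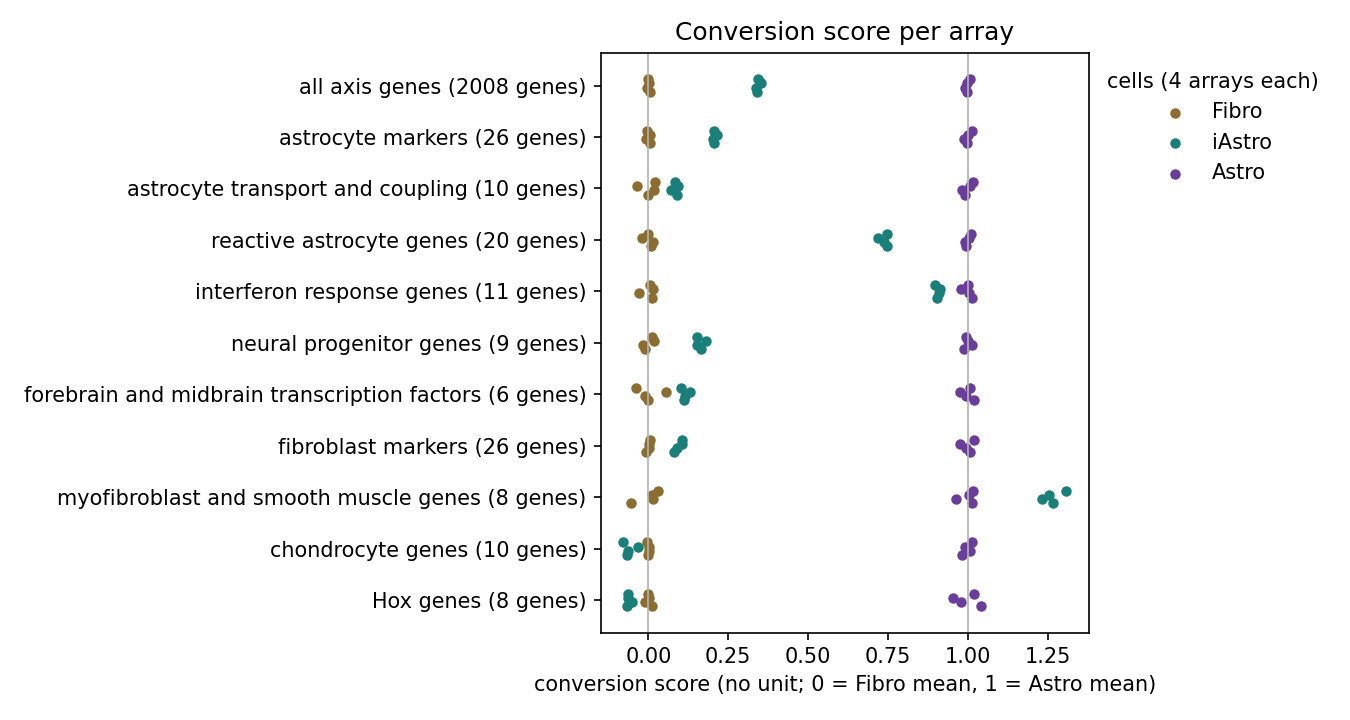
Conversion score of each array (horizontal axis, no unit, 0 at the Fibro mean and 1 at the Astro mean) over all axis genes and over 10 gene lists, each point 1 array. Over all axis genes the iAstro arrays average 0.343, over reactive astrocyte genes 0.738, over fibroblast markers 0.095 and over myofibroblast and smooth muscle genes 1.266.

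Of the 3847 genes higher in Astro than in Fibro, 1764 were also called higher in iAstro than in Fibro (45.9%, 95% exact binomial interval 44.3 to 47.4), 1217 were not called and 866 were lower (22.5%). Of the 4676 genes lower in Astro, 2543 were also lower in iAstro (54.4%, interval 52.9 to 55.8) and 765 were higher (16.4%). The intervals cover counting error alone. Independent lists of these sizes would share 981.8 and 1620 genes. Both comparisons share the Fibro arrays. With the Fibro arrays split between the comparisons, the shares were 44.3% and 49.4% one way and 44.3% and 47.5% the other way. The correlation of both sets of fold changes across genes was 0.445, where shared controls alone gave 0.50 in 100 simulations of unchanged groups against the same Fibro arrays, but the covariance was 0.402 against 0.00362 simulated. Among genes at least 2-fold apart between the control groups, 703 of 1187 higher in Astro (59.2%) and 551 of 821 lower in Astro (67.1%) moved the same way in iAstro. The opposite way moved 169 (14.2%) and 175 (21.3%). Genes that moved towards Astro in iAstro and were not called different from Astro numbered 421 of 3847 (10.9%) and 1142 of 4676 (24.4%). Among genes at least 2-fold apart they numbered 76 of 1187 (6.4%) and 64 of 821 (7.8%).

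In iAstro 3873 genes (31.2% of those tested) were set apart from both control groups, 1872 above both and 2001 below both, and 572 of them lay at least 2-fold from both, 410 above and 162 below. With the floor of 1.2-fold 1750 genes were set apart. The largest excesses over both groups were in the interleukin gene Il17b (99.4-fold over Fibro and 87.1-fold over Astro), Elapor1 (72.8-fold and 70.9-fold), Angptl7 (69.5-fold and 113-fold), the carbonic anhydrase gene Car12 (49.8-fold and 46.3-fold), Col9a1 and Otos (42.1-fold over each). Below both groups lay Cnn1, Pcp4l1 (31.1-fold and 43.3-fold lower), Dner (23.5-fold and 70.1-fold lower), Ramp1 (20.9-fold and 22.9-fold lower), Id4 (10.9-fold and 22.3-fold lower) and Tagln. Of 19 chondrocyte genes 16 lay above both groups, of 24 cell cycle genes 21 lay below both, and of 12 myofibroblast and smooth muscle genes 8 lay below both. Folds against a group that reads between 2.72 and 3.91, as the bacterial control probe sets do, depend on the array's background.

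**Figure D4:**
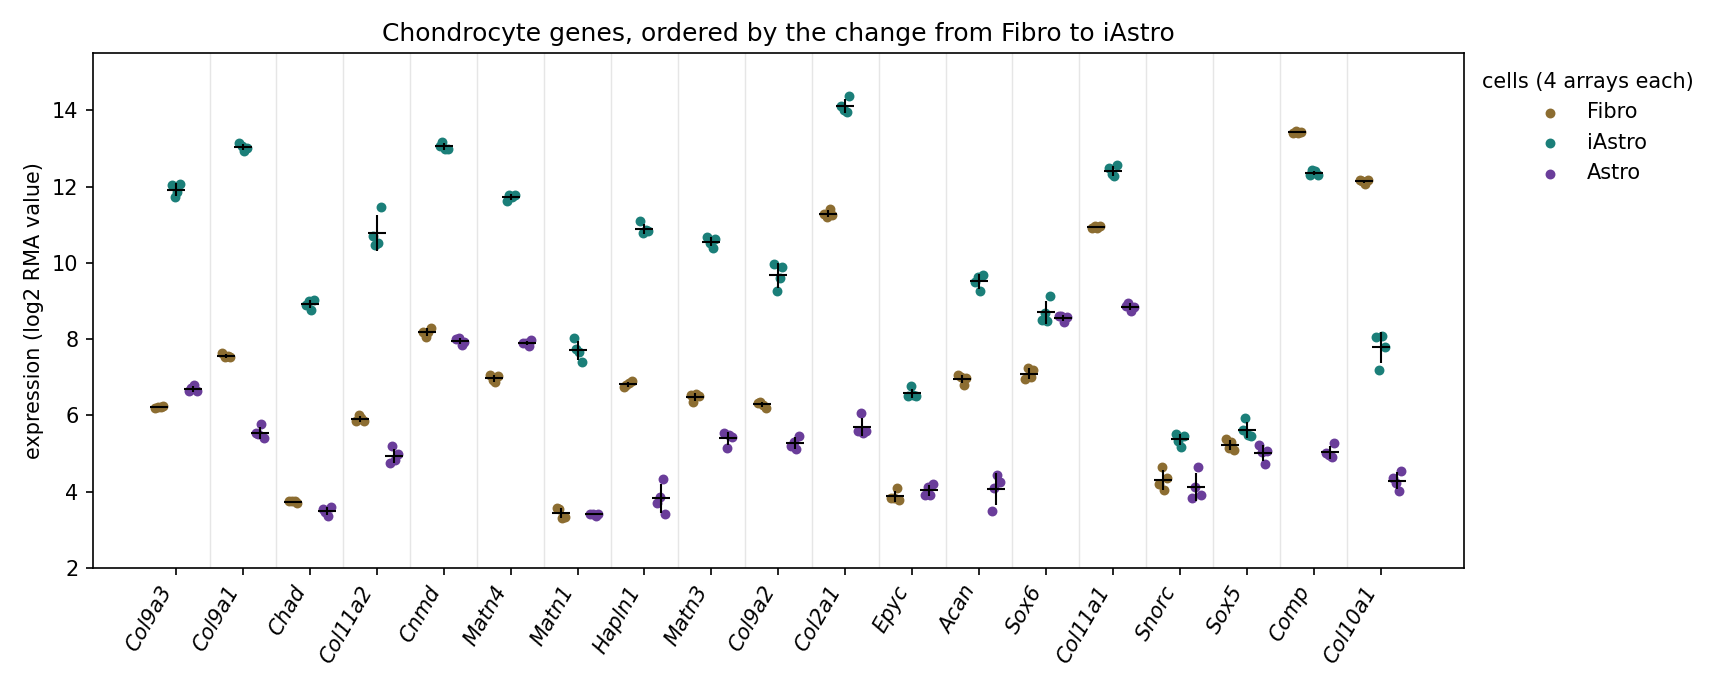
Log2 expression of the 19 measured chondrocyte genes (vertical axis, log2 RMA value) in the 4 arrays of each group, each point 1 array, with the mean (horizontal bar) and SD (vertical bar), ordered by the change from Fibro to iAstro. In 17 genes the iAstro arrays lie above the Fibro arrays, and Comp and Col10a1, at the right, lie below them.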

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

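Within each group of 4 arrays, 429 series of values behind the text were searched for an array far from the other 3, by the gap to the nearest array over the whole range of the group against Dixon's 95% critical value, a search planned in advance. In 22 of them (5.13%) an array stood apart, and chance gives about 1 in 20.

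In the iAstro group, replicate 3 stood apart for A2m (gap over range 0.964; log2 7.78 against 8.15 to 8.16), Prom1 (0.954; 4.86 against 5.19 to 5.21), S100b (0.91; 11.08 against 11.29 to 11.32), Myl9 (0.844; 9.49 against 9.25 to 9.29), Fgfr3 (0.846; 9.38 against 9.60 to 9.64) and the array's upper quartile (0.926; 8.95 against 8.97 to 8.98). Replicate 2 stood apart for Ccnb2 (0.918; 6.95 against 6.73 to 6.75), Hoxa11 (0.865; 8.25 against 8.19 to 8.20) and the Nfia probe set with the largest rise (0.848; 9.06 against 10.8 to 11.11), and replicate 1 for Vim (0.861; 14.13 against 14.12 in the others).

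In the Astro group, replicate 1 stood apart for Ctss (0.877; 8.12 against 8.27 to 8.29), Flt1 (0.925; 5.71 against 6.02 to 6.04) and Rgs5 (0.846; 3.58 against 3.86 to 3.91). Replicate 2 did so for Col2a1 (0.915; 6.06 against 5.55 to 5.59), Foxj1 (0.949; 9.71 against 9.62 in the others) and Id4 (0.977; 11.78 against 11.91 in the others). Replicate 3 did so for Angptl7 (0.851; 5.05 against 4.73 to 4.78) and the second Sox9 probe set (0.963; 8.45 against 8.62 to 8.63).

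In the Fibro group, Abi3bp (0.847; 12.27 against 12.09 to 12.12) and Stmn2 (0.859; 8.23 against 8.13 to 8.14) stood apart in replicate 2, Myl9 in replicate 3 (0.842; 13.59 against 13.67 to 13.69) and Chad in replicate 4 (0.853; 3.70 against 3.75 to 3.76). Of the 12 arrays iAstro replicate 3 held the most such results, 6 of the 22. Without it, Fgfr3 passed the test of iAstro against Astro (0.13, adjusted p = 0.0332), and with all arrays it did not (0.07, adjusted p = 0.321). No cause was sought for these results.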

How the results depend on the processing

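Every alternative here was planned except leaving out iAstro replicates 2 and 4 together, which was chosen after seeing the data. Fewer or more features tested explain the counts with every probe set, and a stricter test those with a floor of 1.2-fold; for the other changes the cause was not tested. Testing every probe set called 11649 (iAstro against Fibro), 13441 (Astro against Fibro, 3092 of them at least 2-fold) and 12471 (iAstro against Astro), with 5918 set apart. The 1.2-fold floor called 3668, 4709 and 4722 genes, with 1750 set apart. The shares of Astro-high genes raised and of Fibro-high genes lowered in iAstro were 43.5% and 50.9% in fits of 8 arrays, 42.8% and 60.3% with medians aligned, 51.5% and 58.3% without dim genes, 39.4% and 41.4% with the floor, and 42.7% and 50.6% without iAstro replicates 2 and 4; array weights gave 52.9% for the latter share. The score of iAstro was 0.284 as a median ratio over genes and 0.354 without dim genes. With the mean of its probe sets Nfia was reversed, higher in iAstro than in Astro (1.93), and without _x or _s probe sets the value of Mcm7 in iAstro against Fibro turned negative without a call (−0.04, adjusted p = 0.543).

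Leaving out 1 array at a time gave 7067 to 7447, 8019 to 8714 and 7610 to 7946 called genes in the 3 comparisons, 1366 to 1387, 2008 to 2016 and 1962 to 2003 of them at least 2-fold, shares of 44.6% to 46.6% and 51.4% to 55.3%, 3686 to 3957 genes set apart, scores of 0.340 to 0.345 and 35 list calls each time. Replicate numbers gave little sign of pairing: 1 of 12 correlations between arrays of like number exceeded 0.1 (range −0.107 to 0.248). It was that of replicate 3 of iAstro and Astro (0.248, at most 0.0317 with other numbers). The check cannot exclude a pairing. With a replicate block 7369, 8484 and 7885 genes, 35 lists and 3828 genes set apart were called. An estimated correlation ended 6 list calls, leaving out dim genes ended 2 and fry added 15. Among 195 tabulated gene comparisons, 4026 values across the alternatives kept direction and side of the threshold, 24 came to pass it, 35 no longer passed, nearly all for Tyms, Des and Slc7a10, and 2 reversed. Genes near the level of the bacterial controls give folds set by background.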

Other observations

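The tests of mixtures, of other cells in the Astro cultures, of cell growth, of introduced Sox9 and of the probe sets were chosen after the results were seen; the splits of the arrays and the tests of array scaling were planned.

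Gene by gene, iAstro followed Astro in some lists and left it in others. Of the 13 interferon response genes higher in Astro than in Fibro, 13 were also higher in iAstro, and 3 of these stayed below Astro. Of the 23 reactive astrocyte genes higher in Astro, 18 rose in iAstro and 1 fell, and across the whole list 10 lay above both control groups and 5 below both. Of the 28 astrocyte markers higher in Astro, 18 rose in iAstro, 8 were not called and 2 fell, and 25 stayed below Astro. Of the 28 fibroblast markers lower in Astro, 12 fell in iAstro and 10 rose instead, and all 28 stayed above Astro.

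Other lists held genes that moved against the direction of Astro. Of the 20 cell cycle genes higher in Astro than in Fibro, 19 were lower in iAstro than in Fibro and 1 was higher, and all 20 lay below Astro. Of the 10 neuron markers higher in Astro, 6 fell in iAstro and 1 rose. Of the 14 Hox genes lower in Astro, 8 rose in iAstro and 1 fell, and all 14 lay above Astro, though the rise of the Hox list lost its call with dim genes left out (adjusted p = 0.193). Of the 6 forebrain and midbrain transcription factors higher in Astro, 3 rose in iAstro and 0 fell. By contrast, the 10 cholesterol synthesis genes lower in Astro than in Fibro were also lower in iAstro than in Fibro, and 10 of the 14 measured lay below both control groups.

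Other splits of the arrays were counted to see whether chance can be excluded. For the called genes of each comparison, 1 of the 35 splits of its 8 arrays into 4 and 4, the real one, gave as many: limma called 7134 genes for iAstro and Fibro, 8896 for Astro and Fibro and 7672 for iAstro and Astro, and 0 in every other split. For the other counts 1 of 100 splits of the 12 arrays into 3 groups of 4, the real one, gave as many. Genes raised in both iAstro and Astro numbered 1764 (highest other split 1310), genes lowered in both 2543 (1325), genes set apart 3873 (3019) and list calls 35 (34). Every other split mixed the cell types, which lie far apart, so a lower count of genes there was bound to follow. The splits thus add nothing to the separation of the groups already seen, and cannot exclude chance. For the list calls another split gave nearly as many, 34.

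The 17 chondrocyte genes that rose in iAstro form the first pattern. With array medians aligned the list's median was 3.33. The array medians spanned only 7.054 to 7.145, so this step could hardly have moved it. Differences of that size are too small to give the rise, but scaling before deposit was not tested. Growth in the share of chondrocyte-like cells of the Fibro cultures, with their makeup unchanged, stays open: 2 members, Col10a1 and Comp, fell by more than 1 on the log2 scale, but which cells expressed them is not known. Introduced Sox9, a regulator of cartilage genes, may have raised these 17 genes, but no group received Sox9 alone, so this cannot be told apart from an effect of the other factors or of infection.

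The second pattern is the position of iAstro between the control groups. A mixture of fully converted cells and unchanged fibroblasts would give 1 share of converted cells for all genes. Of 135 genes at least 16-fold higher in Astro, 37.8% implied a share under 1% and 24.4% a share over 30% (median 2.8%, quartiles 0.0968% to 29.7%). These genes were not limited to astrocyte genes, and included Ctss and Tyrobp of microglia, Stmn2 and Gap43 of neurons and Ifit1 of the interferon response. The spread over all 135 genes argues only against a mixture of unchanged fibroblasts with cells like the whole Astro cultures. Astrocyte markers among them ran from −0.159% (Kcnj10) to 9.87% (Gpr37l1), with Aldoc apart at 133%. Aldh1l1, which read well above background in both Fibro and iAstro (7.16 and 7.28), implied 0.473%, and Fabp7 and Gfap implied 2.8% and 3.57%. Fully converted astrocytes alone would give these markers 1 share. For these markers the spread argues against unchanged fibroblasts mixed with such astrocytes. A mixture with partly changed cells stays open. Microglia and neurons in the Astro cultures might lower the score, and markers of these cells lay below it, at 0.013 and −0.245. Over astrocyte markers alone the score was 0.207, so genes of other cells alone do not explain a position short of Astro. How much they lower the score over all axis genes was not tested. With array medians aligned the score was 0.339, but this step could hardly have moved it. A change of all cells part of the way was not tested.

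The third pattern is the unequal reading of the introduced factors. The Nfia probe sets differed by 5.79 in log2 fold change, and a candidate explanation is that some probe sets lie outside the introduced sequence. Sox9 fell in both of its probe sets, with the smaller fall at −0.89, and loss of expression from the vector by the day of collection could leave no rise, but by itself would not bring the reading below Fibro. These explanations cannot be told apart, since probe positions were not used here and no earlier day was measured.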
